A study of Homo sapiens with 60 samples.

How the data were processed

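RNA of 20 cancer cell lines in 3 conditions was measured on 60 Affymetrix arrays, 1 array per line and condition, and all 60 arrays were used. Per the submitters' processing notes the values were made with RMA, which corrects background, normalizes quantiles between arrays and summarizes probes on the log2 scale. The version, and which arrays were normalized together, are not given in the sources used here. The labels' protocols describe the culture conditions and a standard Affymetrix labelling, and name no hybridization batch or scan date. Sample groups, the cell line and the tissue come from the labels.

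The deposited log2 values had lost most of their decimal points: 1997490 of 1997820 cells, 99.983%, hold digits only. The point was put back after the second digit where a cell starts with 10 to 14 and after the first digit otherwise. Cells of at most 2 digits were read as whole numbers. The rule was checked on the table itself. Values from 10 up with few decimals kept their point, and 0 of the 1613 cells of 4 digits start with 1. The restored values run from 1.77 to 14.42, 154879 cells read as 10 or more, and 18 cells read under 2, in rows whose median is at most 3.28. A true value between 1 and 1.5 would be misread by this rule, which the row medians make a matter of the dimmest probes. Because the cells are not log2 as they stand, the unit was recorded as other, and the tests planned for log2 values were run on the restored values.

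Of 33297 probe rows, 19460 name 1 gene symbol, 1754 name several and 12083 name none in the probe annotation used. Rows with several or no symbols name no gene here and entered only 1 alternative. Symbols were updated through the gene ID, which matched RefSeq for 19429 rows and changed 0 symbols. For the 769 genes with more than 1 row, the row with the highest mean over all arrays stands for the gene. This left 18417 genes, with no filter on intensity. Several genes of interest, TP53, CA9, SERPINE1, HMGCR and STAT1 among them, have no row with a symbol of their own and were not analysed here. There is no count depth in array data, and the number of arrays limits the precision.

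Genes were tested with limma (3.58.1, R 4.3.3) by lmFit and eBayes in 1 fit of all 60 arrays, with the cell line as a fixed block, so that the 3 conditions share 1 estimate of the spread. The comparisons were continuous hypoxia against normoxia, cycling hypoxia against normoxia, and cycling against continuous hypoxia. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 18417 genes of each comparison, and a gene is called at an adjusted p under 0.05. Standard errors are those of the moderated fit, and SDs are over the 20 line differences. Both the standard errors and the p-values rest on a residual spread between lines that is pooled over the 3 conditions. They do not measure the spread of the line differences of 1 comparison alone. With only the 2 groups in the fit, more genes were called in cycling and fewer in continuous hypoxia. The pairing comes from the labels, which give the same 20 lines in each condition. Deviations from the condition means correlated at a median of 0.83 between arrays of 1 line (lowest 0.67 of 60 pairs) and -0.08 between lines, and without the block 596 genes were called higher in continuous hypoxia in place of 3388. For 55 of the 60 arrays the best match was an array of its own line, and 0 pairs of arrays were identical (highest correlation 0.994).

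Gene lists written before the data were examined were tested with limma's camera at a preset correlation of 0.01. Its p-values were adjusted over the 99 tests of 33 lists in 3 comparisons, with the estimated correlation as a check. The lists are HIF targets, glycolysis and lactate export, collagen modifying enzymes, HIF pathway components, the nuclear-encoded respiratory chain, the TCA cycle, the mitochondrial ribosome and biogenesis, cholesterol synthesis, fatty acid synthesis, ATF4 and the integrated stress response, endoplasmic reticulum chaperones and XBP1 targets, and heat shock. Others are NRF2 and oxidative stress, metallothioneins, p53 targets, G1/S and replication, G2/M and mitosis, homologous recombination with Fanconi and mismatch repair, replication-dependent histones, ribosome biogenesis, cytosolic ribosomal proteins, translation factors, splicing, and NF-kB. The last are interferon response, immediate early genes, the epithelial to mesenchymal transition, autophagy and lysosome, iron, and markers of hepatocytes, intestinal epithelium, blood cells, and fibroblasts with endothelium. Lists needed at least 5 measured members. Some lists share genes, so their tests are not independent.

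The design, a set of alternatives and the rule for named genes were also fixed before the data were examined. The text names, from each comparison with normoxia, the 12 largest rises and the 12 largest falls among called genes with the same direction in at least 16 of 20 lines, and from cycling against continuous hypoxia the 10 largest in each direction with the same direction in at least 15 lines. It names up to 4 called members with the lowest adjusted p per list and comparison, the 5 lowest adjusted p of each tissue comparison, and always HIF1A, EPAS1 and VHL. Some were left out for length, and the line-level values of GDF15 and CDKN1A in HCT116 were chosen after the values were seen.

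The mean change of the HIF and glycolysis lists in each line was tested by sign flips over lines with 100000 resamples. Tissue differences were tested with limma on the line differences, colon against other lines and liver against other lines. The changes of both protocols were compared across genes by correlation and covariance. Beside these stand 100 simulations of unchanged groups that share a simulated normoxia group, and 100 splits of the lines into 10 and 10. Chance was gauged by 100 draws, the real grouping included, of labels swapped within lines or of lines regrouped.

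The procedure was tested on simulated data, with changes of known size added to arrays built from the real means and spreads of 18417 genes. Genes were simulated as independent, with the same spread in all conditions. Real genes are correlated, at an estimated 0.716 within the G2/M and mitosis list. The recovery rates and false calls therefore hold for independent genes and may not carry over to the real arrays. For continuous hypoxia against normoxia it recovered 2% of the genes changed by 0.1 log2 units, 74% at 0.25, 96% at 0.5 and 100% at 1, with 5 false calls. For cycling hypoxia against normoxia it recovered 62% at 0.25 and 94% at 0.5, with 6 false calls, and for cycling against continuous hypoxia 52% and 96%, with 7. For the colon comparison in continuous hypoxia it recovered 53% at 0.5 and 98% at 1, with 10 false calls. In the list test a respiratory chain list shifted by 0.2 was called, and so was 1 other list. With independent genes this cannot show how often camera calls unchanged lists of correlated genes.

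The alternatives fixed beforehand changed the block, the test, the variance prior, the normalization, array weights, a filter on the dimmest 30% of genes, the probe chosen per gene, the rows tested, the arrays in the fit, the threshold, and the lines included. Alternatives chosen after seeing the data left out HT29, left out HT29 and HT1080, applied cyclic loess, removed each array's trend with the genomic span of the gene (known for 99.8% of genes), and tested every list by sign flips over lines. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, statmod 1.5.0 served the random block, and matplotlib 3.10.9 drew the figures.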

Results

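Messenger RNA of 20 established human cancer cell lines was profiled on biotin-labelled Affymetrix arrays after 3 culture conditions. Each line spent 24 h in normoxia (21% O2), 24 h in continuous hypoxia (1% O2), or 24 cycles of 0.5 h at 21% O2 and 0.5 h at 1% O2, called cycling hypoxia here. The labels put 7 lines in colon (HCT116, its p53 -/- derivative, HT29, Widr, Colo-205, LoVo and HCT-15), 4 in liver (HepG2, Hep3B, PLC/PRF/5 and SK-HEP-1) and 3 in breast (MCF-7, MDA-MB-231 and T-47D). The others were A549 (lung), siHa (labelled ovary), PC3 (prostate), U373 (brain), A498 (kidney) and HT1080 (labelled epithelium). Each line gave 1 array per condition, 60 arrays in all, so the spread reported is the spread between lines and no line has a replicate of its own. Array medians averaged 6.08 log2 units in normoxia, 6.10 in continuous hypoxia and 6.06 in cycling hypoxia, and 18417 named genes were tested. The precision is limited by the number of arrays.

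Markers stood above those of all lines with other labels in 3 of 4 liver lines and 3 of 7 colon lines. The mean of the hepatocyte markers in the lines labelled liver was 10.83 log2 units in HepG2, 10.17 in Hep3B and 9.09 in PLC/PRF/5 but 4.76 in SK-HEP-1, and the next line was A549 at 5.48. The mean of the intestinal markers was 7.77 in Colo-205, 7.26 in Widr and 6.80 in HT29, and it was 5.23 in HCT116, under the 6.46 of A549. In HCT116 p53 -/- , 15 of the 21 p53 target genes lay below the parent line in all 3 conditions. CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by -1.54 in normoxia, -0.96 in continuous hypoxia and -1.71 in cycling hypoxia on the log2 scale. GDF15, a stress-induced cytokine, differed by -2.72, -2.32 and -2.23 in the same order. These differences rest on 1 array each and were not tested, and TP53 was not analysed here.

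Continuous hypoxia raised the classical targets of the hypoxia-inducible factors (HIF), the transcription factors that oxygen-dependent hydroxylation destines for degradation. Of 36 measured HIF target genes, 35 rose and 0 fell, with a mean log2 change of 1.18 ± 0.41 (SD, n = 20 lines). NDRG1, a hypoxia and stress-responsive gene, rose by 2.46 ± 0.19 log2 units (SE, n = 20 lines), a 5.48-fold change. The mTORC1 inhibitor DDIT4 rose by 2.03 ± 0.15, the mitophagy receptor BNIP3L by 1.91 ± 0.12 and the vasodilator peptide ADM by 1.81 ± 0.15, each in 20 of 20 lines. The histone demethylase KDM3A, itself oxygen dependent, rose by 1.62 ± 0.09 in 20 of 20 lines (adjusted p = 4.1e-18).

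Glycolysis and collagen hydroxylation followed. Of 21 genes of glycolysis and lactate export 20 rose and 0 fell, with a mean of 0.90 ± 0.31 (SD, n = 20 lines). Among them the aldolase ALDOC rose by 2.27 ± 0.19 (SE), PFKFB4, which makes the activator of phosphofructokinase, by 2.20 ± 0.14, the enolase ENO2 by 1.88 ± 0.10, and the glucose transporter SLC2A1 by 1.21 ± 0.07. The camera test gave an adjusted p of 1.85e-35 for the HIF targets and 4.02e-22 for glycolysis, and both calls held with an estimated correlation (adjusted p = 0.0074 and adjusted p = 0.0256). Adjusted over the list alone, 36 HIF targets were higher, and in glycolysis 20 were higher and 1 lower. Of 13 collagen modifying enzymes 9 rose and 0 fell (adjusted p = 2.17e-06, adjusted p = 0.051 with an estimated correlation), led by the prolyl hydroxylases P4HA1 (2.03 ± 0.13) and P4HA2 (1.41 ± 0.10) and the lysyl hydroxylase PLOD2 (1.52 ± 0.11).

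The HIF pathway's own genes moved in both directions. HIF1A, which encodes HIF-1α, fell by 0.47 ± 0.13 (SE) with 13 of 20 lines lower (adjusted p = 0.00246), while EPAS1, which encodes HIF-2α, rose by 0.59 ± 0.10 with 18 of 20 lines higher (adjusted p = 3.39e-06). VHL, the substrate receptor of the ubiquitin ligase for HIF-α, fell by 0.17 ± 0.05 (adjusted p = 0.00427, 14 of 20 lines lower). The HIF hydroxylases EGLN3 and EGLN1 rose by 1.58 ± 0.18 and 0.54 ± 0.07. In total 5 of 10 pathway components rose and 2 fell (adjusted p = 0.0254, adjusted p = 0.194 with an estimated correlation). Without the cell line as a block that list had an adjusted p of 0.0695, and it stayed called in the other 12 alternatives (0.00913 to 0.0388).

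Of 26 genes of ATF4 and the integrated stress response 21 rose and 0 fell (adjusted p = 8.12e-11, adjusted p = 0.218 with an estimated correlation). DDIT3, the transcription factor CHOP, rose by 1.94 ± 0.19 (SE) in 20 of 20 lines, and PPP1R15A, the phosphatase subunit that reverses eIF2α phosphorylation, by 0.81 ± 0.11. Of 9 metallothioneins and zinc response genes 7 rose and 0 fell (adjusted p = 9.48e-06, adjusted p = 0.051 with an estimated correlation), with MT1X at 1.36 ± 0.11 and MT1F at 1.15 ± 0.13. Of 22 immediate early genes 17 rose and 0 fell (adjusted p = 2.02e-08, adjusted p = 0.051 with an estimated correlation), with FOS at 1.00 ± 0.14 and JUN at 0.94 ± 0.10. Of 35 cytosolic ribosomal protein genes 20 rose and 6 fell (adjusted p = 3.05e-05, adjusted p = 0.38 with an estimated correlation), RPS28 by 0.89 ± 0.05 and RPLP2 by 0.72 ± 0.04, whereas RPL19 fell by 0.35. RPS28, RPLP2 and RPL19 moved the same way in cycling hypoxia (0.59, 0.52 and -0.60). The labels name no processing batch, so a batch that follows the condition cannot be told apart from the condition for such shared changes. Of 19 genes of the epithelial to mesenchymal transition 9 rose and 0 fell, including the fibronectin receptor subunit ITGA5 (0.74 ± 0.14). That list's adjusted p was 0.0476 (adjusted p = 0.236 with an estimated correlation), it stayed called in 8 of 12 alternatives (0.0359 to 0.294), and without the cell line as a block it was 0.521.

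The deepest falls lay in the replication-dependent histones, which package newly made DNA. Of 28 measured histone genes 0 rose and 26 fell, with a mean of -0.72 ± 0.34 (SD, n = 20 lines), and the list was lower in 20 of 20 lines (adjusted p = 7.34e-20, adjusted p = 0.0294 with an estimated correlation). H2AC4 fell by 1.39 ± 0.12 (SE), H4C1 by 1.09 ± 0.08 and H2AC13 by 1.08 ± 0.09, each in 20 of 20 lines, and the histone chaperone gene ASF1A fell by 1.06 ± 0.10. Of 39 ribosome biogenesis genes 0 rose and 36 fell (adjusted p = 4e-24, adjusted p = 0.103 with an estimated correlation). RRS1, needed for 60S subunit assembly, fell by 1.29 ± 0.13, RRP15 by 1.02 ± 0.10 and UTP20 by 0.92 ± 0.09. Adjusted over the list alone, 27 histone genes and 37 ribosome biogenesis genes were lower. Histone genes are near-identical copies, so their probes can share signal.

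Lists of replication, mitosis, repair, the mitochondrial ribosome and the TCA cycle fell by smaller amounts. Of 39 G1/S and replication genes 1 rose and 31 fell (adjusted p = 1.44e-10, adjusted p = 0.38 with an estimated correlation), with POLE2, a subunit of DNA polymerase epsilon, at -0.89 ± 0.12 (SE) and the sliding clamp PCNA at -0.67 ± 0.11. Of 34 G2/M and mitosis genes 0 rose and 28 fell (adjusted p = 5.18e-11, adjusted p = 0.375 with an estimated correlation), with CKS2 at -0.68 ± 0.08 and the kinetochore protein CENPF at -0.65 ± 0.10. In homologous recombination, Fanconi and mismatch repair 0 of 19 genes rose and 11 fell (adjusted p = 1.37e-05, adjusted p = 0.413 with an estimated correlation), among them RAD51C at -0.64 ± 0.07. Of 29 genes of the mitochondrial ribosome and biogenesis 1 rose and 26 fell (adjusted p = 2.04e-14, adjusted p = 0.074 with an estimated correlation), and of 15 TCA cycle genes 1 rose and 10 fell (adjusted p = 0.000309, adjusted p = 0.237 with an estimated correlation), with SUCLA2 at -0.57 ± 0.06 and citrate synthase CS at -0.41 ± 0.05.

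Further lists fell in part. In fatty acid synthesis 2 of 12 genes rose and 6 fell (adjusted p = 0.00838, adjusted p = 0.325 with an estimated correlation): FASN fell by 0.93 ± 0.13 (SE) and ACACA by 0.85 ± 0.09, while the desaturase SCD rose by 0.57 ± 0.09. Of 13 heat shock genes 0 rose and 8 fell (adjusted p = 0.000239, adjusted p = 0.393 with an estimated correlation), with HSPH1 at -0.63 ± 0.11. Of 48 splicing factors and mRNA processing genes 6 rose and 32 fell (adjusted p = 2.17e-06, adjusted p = 0.325 with an estimated correlation), with SNRPD1 at -0.77 ± 0.09. Of 28 translation initiation and elongation factors 3 rose and 13 fell (adjusted p = 0.0213, adjusted p = 0.478 with an estimated correlation), with EIF2B3 at -0.75 ± 0.09. This last call held in 10 of 12 alternatives (adjusted p = 0.00119 to 0.0879).

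The other 13 lists did not pass the camera test in continuous hypoxia. Their counts of higher and lower members were 11 and 6 of 33 in the nuclear-encoded respiratory chain (adjusted p = 0.261), 3 and 3 of 18 in cholesterol synthesis (0.498), and 6 and 4 of 17 among endoplasmic reticulum chaperones and XBP1 targets (0.258). They were 6 and 3 of 23 among NRF2 and oxidative stress genes (adjusted p = 0.69), 8 and 4 of 21 among p53 targets (0.156), and 7 and 1 of 22 among NF-kB and inflammatory genes (0.209). Interferon response genes gave 7 and 13 of 28 (adjusted p = 0.404), autophagy and lysosome genes 11 and 5 of 24 (0.0749), and iron uptake and storage 4 and 0 of 11 (0.154). Among the marker lists, hepatocyte markers gave 5 and 0 of 19 (adjusted p = 0.581), intestinal markers 4 and 0 of 13 (0.12), blood cell markers 2 and 0 of 15 (0.576), and fibroblast and endothelial markers 4 and 0 of 18 (0.258). Autophagy and lysosome genes gained a call in 4 of 12 alternatives (0.0228 to 0.0921), and p53 targets in 2 of 12 alternatives (0.0389 to 0.26). Within these lists, GDF15 rose by 1.11 ± 0.14 (SE), the lysosomal protein CD68 by 0.66 ± 0.09 and the autophagosome protein MAP1LC3B by 0.78 ± 0.09, and the interferon-induced IFIT1 fell by 0.69.

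In the limma fit with the cell line as a block, 3388 genes were higher and 3548 lower in continuous hypoxia, 37.7% of those tested, and the median size of a called change was 0.25 log2 units. At least a 1.5-fold change was reached by 253 of the higher and 238 of the lower genes. Without the block 596 and 718 genes were called, since the differences between lines then enter the spread.

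**Figure D1:**
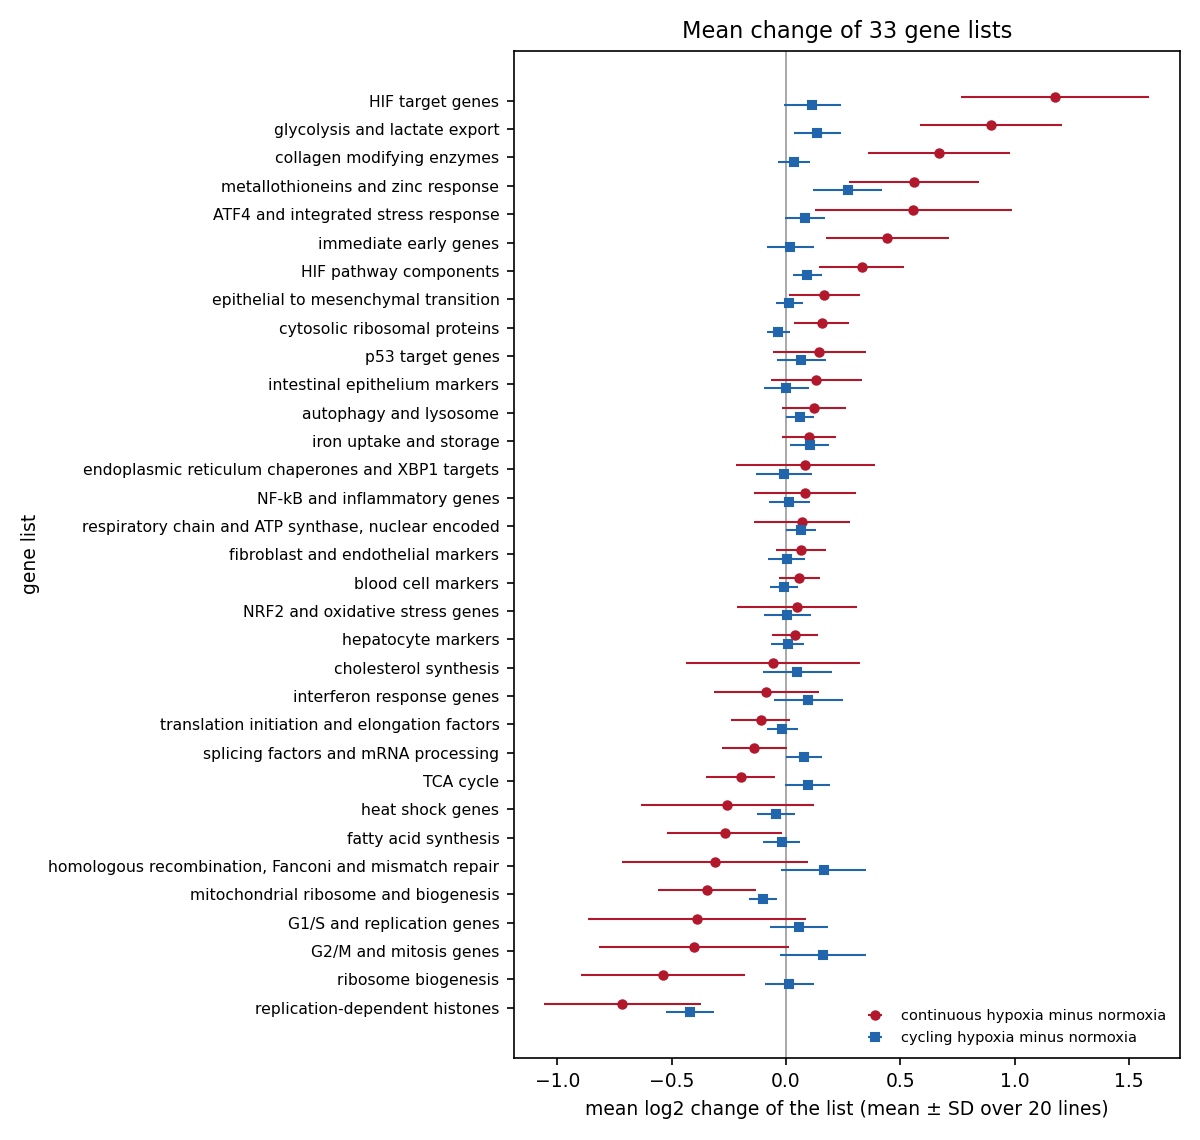
Mean log2 change of each of the 33 gene lists against normoxia, with bars for the SD over 20 lines; circles show continuous hypoxia and squares cycling hypoxia. HIF target genes lie at 1.18 in continuous and 0.12 in cycling hypoxia, and replication-dependent histones at -0.72 and -0.42.

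The largest rises in cycling hypoxia were those of RBX1, the RING subunit of cullin ubiquitin ligases, by 1.03 ± 0.04 log2 units (SE, n = 20 lines), the histone H2BC12, by 1.00 ± 0.11, TMEM258, a subunit of the oligosaccharyltransferase, by 0.96 ± 0.05, and LSM5, a component of the U6 snRNA-binding ring, by 0.94 ± 0.07, each higher in 20 of 20 lines. The largest fall was that of RPPH1, the RNA component of ribonuclease P, by 1.71 ± 0.08 (20 of 20 lines lower, adjusted p = 4.21e-22). Replication-dependent histones fell here too: 0 of 28 rose and 22 fell, with a mean of -0.42 ± 0.10 (SD, n = 20 lines). H2BC12, which rose, is not on this list of 28 genes. HIF target genes averaged 0.12 ± 0.12 (SD, n = 20 lines), with 7 of 36 higher and 1 lower.

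Other large rises included those of the Mediator subunit MED31 (0.84 ± 0.06, SE), the ESCRT-III protein CHMP1B (0.82 ± 0.06), DDIT3 (0.81 ± 0.19) and NPC2, which carries cholesterol in lysosomes (0.77 ± 0.06), each in 20 of 20 lines. The SE of DDIT3 uses the spread pooled over all conditions and was 0.052 with only the cycling and normoxia arrays in the fit. TGIF1, a repressor of TGF-beta signalling (0.83 ± 0.09), and the spliceosome protein PLRG1 (0.80 ± 0.11) rose in 19 of 20 lines, HT29 being lower at -0.08 and -0.49. Beside the histones H4C1 (-0.95 ± 0.08) and H2AC4 (-0.93 ± 0.12), the falls included SSNA1, a microtubule-associated protein (-0.82 ± 0.06), and the small nucleolar and Cajal body RNAs SNORA21 (-0.78 ± 0.12) and SCARNA5 (-0.82 ± 0.09). The labels name no processing batch, so a batch that follows the condition and the condition itself cannot be told apart for genes that moved evenly in all lines.

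Among the lists fixed in advance, camera called 4. Of 100 swaps of labels within lines, the real labels included, 53 gave at least 4 called lists. Chance could thus not be excluded for this count. The histones had an adjusted p of 7.33e-13 (adjusted p = 0.074 with an estimated correlation, and 23 lower when adjusted over the list alone). Of 29 genes of the mitochondrial ribosome and biogenesis 2 rose and 9 fell (adjusted p = 0.00208, adjusted p = 0.533 with an estimated correlation), with MRPS7 at -0.45 ± 0.05 (SE). Of 9 metallothioneins and zinc response genes 6 rose and 0 fell (adjusted p = 0.00976, adjusted p = 0.286 with an estimated correlation), with MT1F at 0.57 ± 0.13 and MTF1, the zinc-sensing regulator of metallothionein genes, at 0.38 ± 0.06. Of 34 G2/M and mitosis genes 12 rose and 1 fell (adjusted p = 0.00717, adjusted p = 0.791 with an estimated correlation), with the securin PTTG1 at 0.40 ± 0.07 and UBE2C at 0.39 ± 0.07, and CKS2 at -0.35 ± 0.08. Without the cell line as a block the metallothionein list had an adjusted p of 0.0613, and it stayed called in the other 12 alternatives (0.00338 to 0.0327). Adjusted over the list alone, 13 G2/M genes were higher and 1 lower, and 7 metallothionein list genes were higher.

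HIF targets and glycolysis did not pass the camera test in cycling hypoxia (adjusted p = 0.33 and 0.0889). The called HIF targets included FAM162A (0.59 ± 0.12, SE), BNIP3L (0.52 ± 0.12) and WSB1 (0.38 ± 0.09), while JMJD6, a 2-oxoglutarate oxygenase, fell by 0.35 ± 0.06. In glycolysis 5 of 21 genes rose, among them PDK1, which restrains pyruvate dehydrogenase (0.59 ± 0.14), SLC2A1 (0.34 ± 0.07) and LDHA (0.29 ± 0.07), and PFKL fell by 0.34 ± 0.06. Adjusted over the list alone, 7 HIF targets were higher and 1 lower, and 5 glycolysis genes were higher and 1 lower. The shared spread of the 3 conditions weighs on these counts. With only the cycling and normoxia arrays in the fit, 17 HIF targets were higher and 3 lower, 12 glycolysis genes were higher and 1 lower, and the adjusted p of the lists was 0.0932 and 0.00795.

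VHL fell by 0.32 ± 0.05 (SE) in 20 of 20 lines (adjusted p = 7.04e-07), and the HIF-α partner ARNT rose by 0.33 ± 0.04 in 20 of 20 lines. HIF1A differed by 0.23 ± 0.13 and was higher in 18 of 20 lines (adjusted p = 0.162). That gene was called with only the 2 groups in the fit (adjusted p = 0.000105) and with array weights (0.0199), within a range of 0.000105 to 0.276 over the alternatives that kept the line as a block and 0.791 without it. EPAS1 differed by 0.10 ± 0.10 (adjusted p = 0.454).

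The remaining lists were not called by camera, with adjusted p-values from 0.0631 to 0.863 over 29 lists. In some of them members moved in opposite directions. In the respiratory chain 13 of 33 genes rose and 10 fell (adjusted p = 0.209), with SDHC at 0.63 ± 0.05 (SE) and SDHD at 0.49 ± 0.05, both subunits of succinate dehydrogenase. Of 35 cytosolic ribosomal protein genes 8 rose and 15 fell (adjusted p = 0.072), with RPS28 at 0.59 ± 0.05 and RPL19 at -0.60 ± 0.04. In homologous recombination 7 of 19 rose and 1 fell (adjusted p = 0.0641), and of 48 splicing genes 14 rose and 6 fell (adjusted p = 0.0631). Calls were gained for homologous recombination in 3 of 12 alternatives (0.0122 to 0.18), with 13 higher and 3 lower and an adjusted p of 0.0122 with only the 2 groups in the fit. They were gained for splicing in 5 of 12 (0.0192 to 0.463) and in the fit without the cell line as a block (0.00327), and for cytosolic ribosomal proteins in 3 of 12 alternatives (0.0171 to 0.107). Of 39 ribosome biogenesis genes 7 rose and 6 fell (adjusted p = 0.841). For 13 of these lists the mean, the median and the test did not share a sign, ribosome biogenesis and collagen modifying enzymes among them.

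In limma 3492 genes were higher and 2594 lower in cycling hypoxia, 33.0% of those tested, with a median size of 0.23 log2 units. A 1.5-fold change was reached by 70 of the higher and 32 of the lower genes. Without the cell line as a block 293 and 575 genes were called, and with array weights the lower genes numbered 4031. With only the cycling and normoxia arrays in the fit 4814 genes were higher and 3505 lower.

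Set against continuous hypoxia, cycling hypoxia left HIF targets lower and ribosome biogenesis genes higher. Of 36 HIF target genes 0 were higher and 36 lower, with a mean difference of -1.06 ± 0.37 (SD, n = 20 lines). NDRG1 differed by -2.24 ± 0.19 (SE), DDIT4 by -2.01 ± 0.15, ALDOC by -2.00 ± 0.19, and ANGPTL4, a lipoprotein lipase inhibitor, by -1.63 ± 0.17. Of 39 ribosome biogenesis genes 35 were higher and 1 lower (adjusted p = 5.16e-16, adjusted p = 0.237 with an estimated correlation), with UTP20 at 0.97 ± 0.09 and RRP1B at 0.76 ± 0.06. The genes with the largest positive differences included the histone H2BC14 (1.36 ± 0.17), the Wnt antagonist DKK1 (1.23 ± 0.17), POLE2 (1.18 ± 0.12) and the nicotinic receptor subunit CHRNA5 (1.16 ± 0.09).

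The HIF target list was called (adjusted p = 3.12e-24) and held with an estimated correlation (adjusted p = 0.0256). In glycolysis 1 of 21 genes was higher and 20 were lower (adjusted p = 3.34e-13, adjusted p = 0.074 with an estimated correlation). Of 13 collagen modifying enzymes 0 were higher and 11 lower (adjusted p = 1.51e-06, adjusted p = 0.051 with an estimated correlation). In the ATF4 list 0 of 26 genes were higher and 18 lower (adjusted p = 8.75e-07, adjusted p = 0.357 with an estimated correlation), with the transcription factor ATF3 at -0.82 ± 0.11 (SE). Of 22 immediate early genes 0 were higher and 15 lower (adjusted p = 1.59e-06, adjusted p = 0.074 with an estimated correlation), with JUN at -0.77 ± 0.10. Of 35 cytosolic ribosomal protein genes 3 were higher and 24 lower (adjusted p = 3.91e-07, adjusted p = 0.286 with an estimated correlation), with RPS9 at -0.54 ± 0.05. Of 9 metallothioneins and zinc response genes 1 was higher and 6 lower (adjusted p = 0.0449, adjusted p = 0.38 with an estimated correlation), with MT1X at -0.88 ± 0.11 and MTF1 at 0.39 ± 0.06. This last call held in 8 of 12 alternatives (adjusted p = 0.0209 to 0.166) and gave 0.421 without the cell line as a block.

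Lists of the cell cycle, repair, the TCA cycle, the mitochondrial ribosome and splicing were higher in cycling than in continuous hypoxia. Of 34 G2/M and mitosis genes 32 were higher and 0 lower (adjusted p = 5.62e-13, adjusted p = 0.325 with an estimated correlation), with the mitotic kinase PLK1 at 1.02 ± 0.11 (SE) and CCNB1 at 0.85 ± 0.09. Of 39 G1/S and replication genes 34 were higher and 1 lower (adjusted p = 6.59e-08, adjusted p = 0.478 with an estimated correlation). In homologous recombination, Fanconi and mismatch repair 16 of 19 were higher and 0 lower (adjusted p = 1.04e-06, adjusted p = 0.368 with an estimated correlation), with RAD51C at 0.81 ± 0.07 and XRCC2 at 0.73 ± 0.10. Of 15 TCA cycle genes 12 were higher and 0 lower (adjusted p = 2.16e-05, adjusted p = 0.152 with an estimated correlation), with the isocitrate dehydrogenase subunit IDH3A at 0.76 ± 0.08. Of 29 genes of the mitochondrial ribosome and biogenesis 19 were higher and 2 lower (adjusted p = 2.16e-05, adjusted p = 0.379 with an estimated correlation). In splicing and mRNA processing 30 of 48 genes were higher and 1 lower (adjusted p = 2.27e-07, adjusted p = 0.286 with an estimated correlation).

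Of 28 replication-dependent histones 15 were higher and 0 lower in cycling than in continuous hypoxia (adjusted p = 0.0032, adjusted p = 0.52 with an estimated correlation). Of 13 heat shock genes 7 were higher and 0 lower (adjusted p = 0.012, adjusted p = 0.611 with an estimated correlation), with HSPH1 at 0.67 ± 0.11 (SE). Both calls held in 11 of 12 alternatives, over ranges of adjusted p of 0.00136 to 0.0595 and 0.00143 to 0.0659. HIF1A was higher by 0.71 ± 0.13 in 19 of 20 lines (adjusted p = 9.35e-06), EPAS1 lower by a log2 difference of -0.49 ± 0.10 (adjusted p = 4.25e-05), and VHL by -0.16 ± 0.05 (adjusted p = 0.0048). The VHL call held in 11 of 12 alternatives (adjusted p = 0.000132 to 0.0508). The other 17 lists were not called by camera, with adjusted p-values from 0.0641 to 0.841, and in the respiratory chain (14 higher and 13 lower of 33) and in iron uptake and storage the mean, the median and the test did not share a sign.

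In limma 5025 genes were higher and 4673 lower in cycling than in continuous hypoxia, 52.7% of those tested. A 1.5-fold difference was reached by 560 of the higher and 185 of the lower genes. Without the cell line as a block 1632 and 1816 genes were called.

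The mean HIF target change in continuous hypoxia was above 0 in 20 of 20 lines, to different extents. The mean response of the 36 genes ran from 0.25 in HT1080 and 0.60 in A498, a renal line that lacks functional VHL, to 2.02 in HepG2. In cycling hypoxia it ran from -0.13 in HCT-15 to 0.39 in Colo-205 and was above 0 in 17 of 20 lines. The glycolysis list rose by 0.27 in HT1080 and by 1.46 in MCF-7 in continuous hypoxia, and in cycling hypoxia its mean was 0.14 ± 0.10 (SD, n = 20 lines), above 0 in 19 of 20 lines. In a two-sided sign-flip permutation test over lines with 100000 resamples, both lists in continuous hypoxia and both differences between the protocols gave p = 1e-05, the smallest this test can give. In cycling hypoxia p was 0.00039 for the HIF targets and 2e-05 for glycolysis. This test asks whether the mean of a list differs from 0 over lines, whereas camera sets the list against the other genes.

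**Figure D2:**
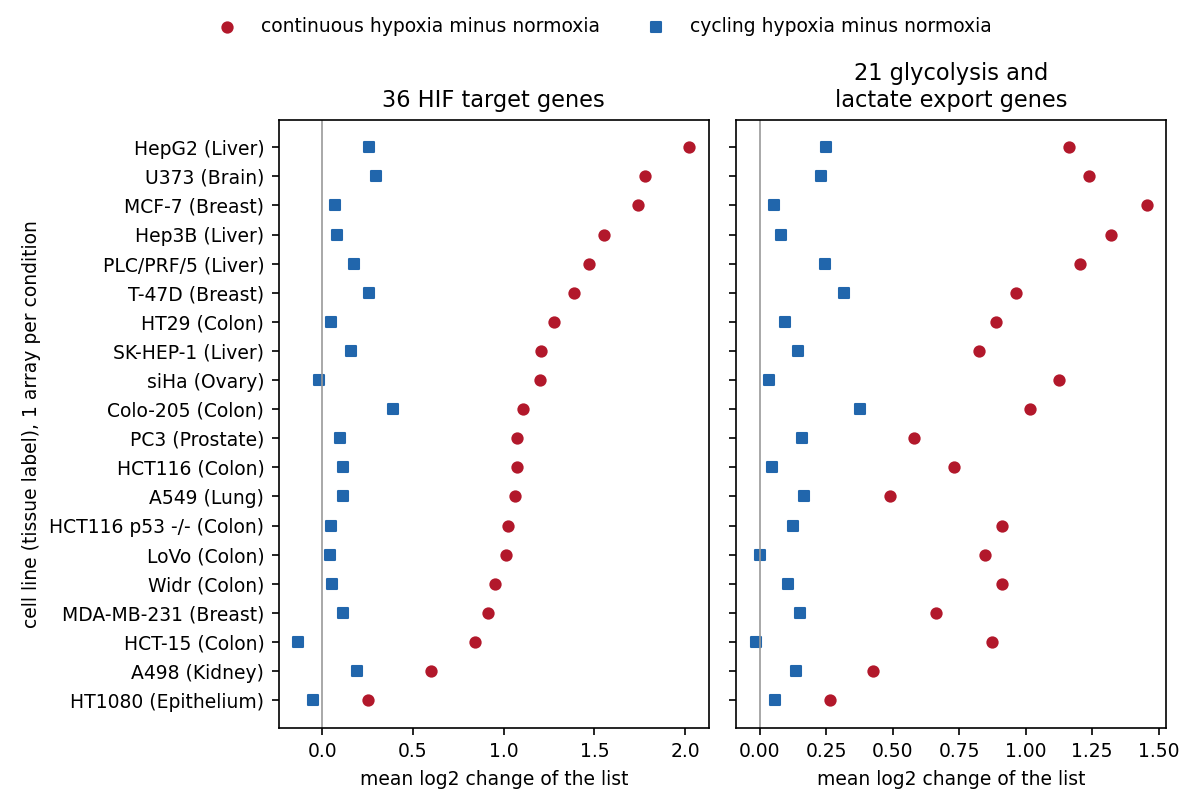
Mean log2 change of the 36 HIF target genes (left) and the 21 glycolysis and lactate export genes (right) in each line, with 1 array per line and condition; circles show continuous and squares cycling hypoxia against normoxia. The HIF response to continuous hypoxia lies above that to cycling hypoxia in 20 of 20 lines and is lowest in HT1080 at 0.25.

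Across genes, the changes of the 2 protocols had a Pearson correlation of 0.17 (jackknife SE over lines 0.05, 0.148 to 0.196 with each line left out in turn). Genes are not independent replicates, and both comparisons use the same normoxia arrays. Simulated unchanged groups that shared a simulated normoxia group gave a correlation of 0.50 and a covariance of 0.00227, beside an observed covariance of 0.00667. The shared group and the equal spreads fix the simulated correlation at 0.50, so it is no yardstick for the observed correlation. With continuous hypoxia taken from 10 lines and cycling hypoxia from the other 10, the correlation averaged 0.12 ± 0.11 (SD over 100 splits) and the covariance 0.00489 ± 0.00404. In direction, 949 genes rose in both protocols and 740 fell in both, where independent lists would share 642 and 500. The genes that rose in continuous and fell in cycling hypoxia numbered 234, beside 477 for independent lists. Those that fell in continuous and rose in cycling hypoxia numbered 781, beside 673. The shared normoxia arrays favour the same direction in both, and the overlap was not tested. Without the derived lines HCT116 p53 -/- and Widr the correlation was 0.22.

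**Figure D3:**
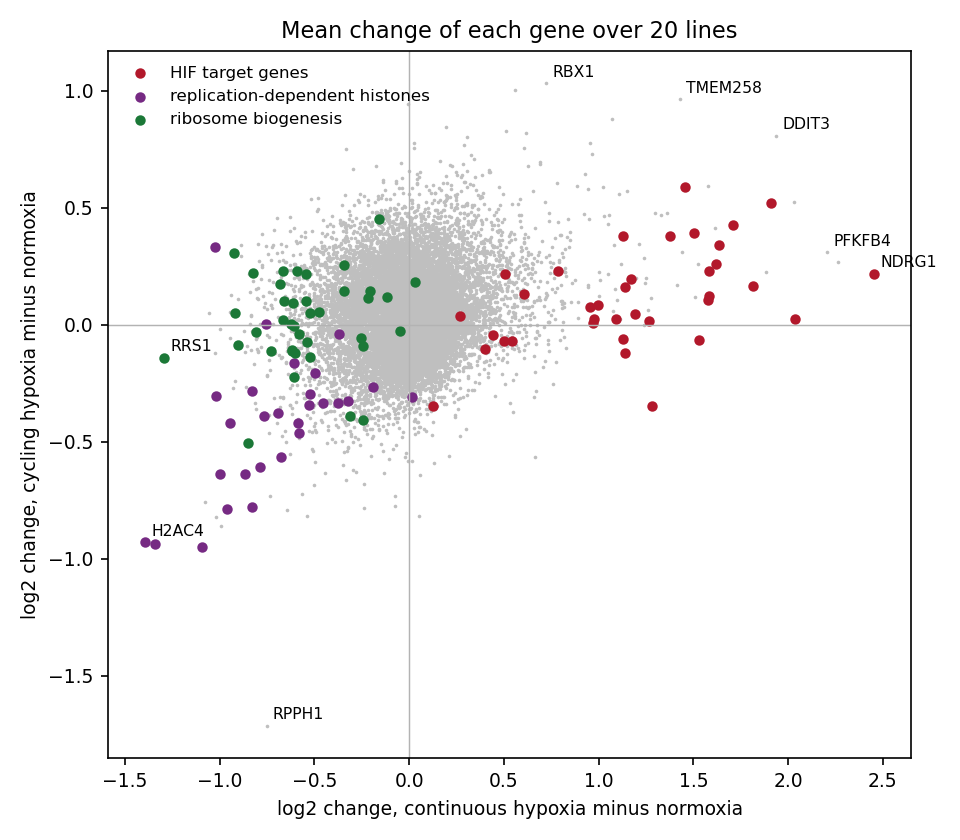
Log2 change of each of 18417 genes in continuous (horizontal axis) and cycling hypoxia (vertical axis) against normoxia, each point the mean over 20 lines. HIF target genes spread along the horizontal axis, with NDRG1 at 2.46 and 0.22, while RPPH1 has the lowest cycling change at -1.71.

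Tissue labels were compared through the change of each line. For the 7 colon lines against the 13 others, limma called 0 genes in continuous hypoxia, with 2711 at an unadjusted p under 0.05 where 921 are expected by chance (lowest adjusted p = 0.0551). In cycling hypoxia it called 0, with 1239 at an unadjusted p under 0.05 (lowest adjusted p = 0.263). For the 4 liver lines against the 16 others, 8 genes differed in continuous hypoxia, 6 with the higher change in liver lines, and in cycling hypoxia 0, with 956 at an unadjusted p under 0.05 (lowest adjusted p = 0.0604). AGTR1, the angiotensin II receptor, rose by 1.04 ± 0.40 (SD) in the liver lines and averaged -0.004 ± 0.24 in the others, a difference of 1.04 ± 0.15 (SE; limma, adjusted p = 0.00895). The lysyl oxidase LOXL4 differed by 0.83 ± 0.13 (adjusted p = 0.0108), histidine ammonia lyase HAL by 1.37 ± 0.22 (adjusted p = 0.0108), and prothrombin F2 by 1.24 ± 0.20 (adjusted p = 0.0132). Each of these was higher in 4 of 4 liver lines. The mechanosensitive channel PIEZO2 differed by -1.04 ± 0.19 (adjusted p = 0.0354) and was higher in 0 of 4 liver lines. The test pooled the spread of all lines, while for each of these genes the SD was larger in the liver lines than in the others. It was 0.91 beside 0.21 for HAL and 0.71 beside 0.28 for F2. With 4 lines in the smaller group, these adjusted p-values can be too small. The liver count moved between 4 and 14 over the alternatives.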

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

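In this part, the split tests for the colon lines and for the liver lines in cycling hypoxia were chosen after the result was seen.

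Colo-205 stood apart from the other colon lines in cycling hypoxia. Its mean change of the glycolysis and lactate export list was 0.377, and the next colon line lay at 0.125, so the gap took 0.643 of the range over 7 lines. Of 28 groups of lines tested in this way 1 had such a line, where chance gives about 1 in 20. Its HIF target mean, 0.392, was also the highest of the 20 lines in cycling hypoxia. No explanation was tested.

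The response to continuous hypoxia differed between liver and other lines in 8 genes by the test of the difference itself. Among 100 splits of the 20 lines into 4 and 16, 3 gave at least 8 genes, the real one included. This lies under the 0.05 level, but without adjustment for the other tissue comparisons. The highest other split called 401, so regrouped lines can far exceed 8 genes, and chance is not firmly excluded. That split points to a structure of the samples that was not tested. The differences, liver minus other lines, were 1.04 for AGTR1, 0.834 for LOXL4, 1.37 for HAL, 1.243 for F2 and -1.042 for PIEZO2. SULT2A1 differed by -1.253, TM4SF5 by 1.36 and APOM by 1.059, and these were chosen after their values were seen. HAL, F2, SULT2A1 and APOM are genes of hepatocyte function. HepG2, Hep3B and PLC/PRF/5 had hepatocyte marker means of 9.09 or more, so a floor of dim probes in the other lines may enter these differences. With the dimmest 30% of genes left out, 4 of the genes tested were called.

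For the remaining tissue comparisons limma called 0 genes, with 2711 for colon lines in continuous hypoxia, 1239 for colon lines in cycling hypoxia and 956 for liver lines in cycling hypoxia at an unadjusted p under 0.05 (921 expected by chance). Every split calls at least 0 genes, so the 100 of 100 reached in each case was fixed by the count of 0 and says nothing about chance. The highest other split called 1 gene for colon lines in continuous hypoxia, 2526 for colon lines in cycling hypoxia and 399 for liver lines in cycling hypoxia. The splits with 2526 and 399 genes point to a structure of the samples, and which lines make it was not tested.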

How the results depend on the processing

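The settings that leave out HT29 or HT29 and HT1080, cyclic loess and the span trend were chosen after seeing the data. The count of called genes depended strongly on whether the cell line was a block. Without it 596 genes were higher and 718 lower in continuous hypoxia, 293 and 575 in cycling hypoxia, and 1632 and 1816 in cycling against continuous hypoxia. The unpaired Welch test, which also leaves line differences in the spread, gave 483 and 587, 361 and 779, and 1387 and 1524. Requiring a 1.5-fold change left 253 and 238, 70 and 32, and 560 and 185. An adjusted p under 0.01 left 1619 lower genes in cycling hypoxia. Array weights gave 4031 lower genes in cycling hypoxia, and the cause was not tested. Testing every probe row, which counts rows of unnamed probes as well, gave 5798 higher and 5776 lower in continuous hypoxia, 5144 lower in cycling hypoxia and 8271 lower in cycling against continuous hypoxia. All other counts of called genes under the alternatives run stayed within 1.5 times, and no scaling moved the share of higher among called genes by over 10 percentage points. Which protocol called more genes depended on the fit. The main fit called 6936 genes in continuous and 6086 in cycling hypoxia. With only the 2 groups in the fit the counts were 5864 and 8319. The paired Wilcoxon signed-rank test gave 5367 and 7660, and array weights gave 6175 and 8896.

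The tissue counts were small and moved easily. With arrays centred on the median, 2 genes differed for colon lines in continuous hypoxia, 14 for liver lines in continuous hypoxia and 2 for liver lines in cycling hypoxia, and the cause was not tested. Without the dimmest 30% of genes the liver counts were 4 and 1, with fewer genes tested. Without HCT116 p53 -/- and Widr 1 gene differed for liver lines in cycling hypoxia, and the correlation of the changes of both protocols was 0.2246. Without A498 the liver count in continuous hypoxia was 5. Without HT29 and HT1080 it was 4, and the colon counts were 3 in continuous and 2 in cycling hypoxia. These settings have fewer lines.

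The mean HIF target and glycolysis responses kept their direction and their side of the threshold in every alternative run for them. Of 425 results for named genes, 1 reversed: P4HB in cycling hypoxia, -0.14 with the probe of highest mean, was 0.2568 (adjusted p = 0.00106) with the probe of widest spread, a different probe of the gene, within a range of adjusted p of 0.000356 to 0.483. Without the cell line as a block 196 of these results lost their call and 229 did not change, and with the line as a random block 28 lost it. Of the 99 list results, 94 were unchanged without the block, 4 lost their call and 1 gained it, and 96 were unchanged with a random block. The filter on dim genes gives no value for 21 gene results and 3 list results. Arrays centred on the median changed 0 of 99 list results.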

Other observations

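In this part, the batch test, the test of the HT29 cycling array against other lines, the tests of the HT29 and HT1080 normoxia arrays, the test of the HT1080 histones, the weighing of a batch in the HT29 histone test, and the corrections on the evenly moving genes were chosen after the result was seen, as were cyclic loess, the span trend and the sign flips for all lists.

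Most microRNA and long noncoding RNA genes were not called, and the classes were chosen after their values were seen. Of 173 microRNA genes 46 rose, 11 fell and 116 were not called in continuous hypoxia, while 7 rose, 35 fell and 131 were not called in cycling hypoxia. The medians, 0.066 and -0.023, were small beside SDs over genes of 0.175 and 0.165. Of 632 long noncoding RNA genes 117 rose, 39 fell and 476 were not called in continuous hypoxia, and 32 rose, 107 fell and 493 were not called in cycling hypoxia. MIR15A rose by 0.88 ± 0.13 (SE) in 20 of 20 lines in cycling hypoxia. No enrichment test was run, so these are counts of genes and not a result for either class.

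Of 33 respiratory chain genes 14 were higher and 13 lower in cycling than in continuous hypoxia (camera adjusted p = 0.841). NDUFA1, a complex I subunit, rose by 0.76 ± 0.09 (SE) in continuous hypoxia and was lower in cycling than in continuous hypoxia (-1.01 ± 0.09), as were the cytochrome oxidase subunits COX5B (-0.63 ± 0.07) and COX6C (-0.48 ± 0.05). The ATP synthase subunit ATP5F1C was higher in cycling hypoxia (0.35 ± 0.04). Of 28 interferon response genes 15 were higher and 7 lower (camera adjusted p = 0.203, sign flips over lines adjusted p = 0.00874), with IFIT1 at 0.96 ± 0.12 and PARP9 at 0.84 ± 0.09 in cycling against continuous hypoxia and ISG20 at -0.44 ± 0.06.

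Of 219 called genes with a cycling change of at least 0.5 log2 units, 22 had an SD over lines of at most 0.25 times their mean. TMEM258 changed by 0.963 ± 0.161 (SD over lines) in cycling and 1.428 ± 0.263 in continuous hypoxia, and RBX1 by 1.033 ± 0.141 and 0.722 ± 0.236. All 22 stayed called in their direction after cyclic loess (median size 0.637 beside 0.64), as did 24 of the 24 largest cycling changes, of which 8 are among the 22. Both sets were chosen for even or large changes, so their calls could hardly be lost. The sizes show only that a smooth trend with signal makes up little of these changes. After removal of the trend with gene span 22 of 22 and 24 of 24 also stayed, at median sizes of 0.641 beside 0.64 and 0.835 beside 0.824. That trend thus makes up little of these changes either. The rank correlation of change with span went from 0.238 to 0.021, which the removal itself brings about. A processing batch that follows the condition stays open: the SD over lines divided by the mean had a median of 0.405 over the 100 largest cycling changes and 0.57 over the continuous ones, which a batch or a uniform effect of exposure could both give, and these cannot be told apart without batch labels.

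HT29 lacked part of the cycling change of the other lines: the slope of its change on theirs over 200 genes was 0.133 beside a mean of 0.963, yet 14 of the 24 largest cycling genes changed in HT29 by over 0.5 times the mean of the others, and 21 in the same direction. Its histones had a mean log2 change of -0.287 ± 0.066 (SE over 28 genes, whose probes can share signal), but exposure and a batch that follows the condition cannot be told apart for genes that fall this evenly over lines, so unexposed cells stay open. The slope of its continuous change, 1.08, argues against cells of continuous hypoxia on its normoxia array. It says little about cells of cycling hypoxia or of normoxic Widr there. Over the 18417 genes the HT29 cycling array correlated at 0.9922 with its own normoxia array and at most 0.9315 with lines other than Widr, which argues against an array of an unrelated line. Widr, a related line, stays open, at 0.9841 over these genes and 0.9869 over all probes, where the highest with HT29 was 0.9913. A partial exposure or a biological difference of this line may also remain, and neither was tested.

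HT1080 had the weakest HIF response to continuous hypoxia, 0.251, with 26 of 36 members higher. Its histones had a mean change of -0.426 ± 0.124 (SE over 28 genes), which a batch that follows the condition could give in unexposed cells too. Unexposed or partly exposed cells stay open, and its ribosome biogenesis genes had a mean change of 0.199 where the mean over lines was -0.538. A high baseline also stays open: its normoxic HIF target mean lay 1.446 SDs above the other lines, though PC3 had the highest level of all lines (8.619) and a HIF response of 1.071. The difference between cycling and continuous hypoxia, -0.304, uses no normoxia array and argues against a misplaced normoxia array.

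Swaps of labels within lines, 100 drawn for each comparison with the real one, exclude chance for the counts of called genes: 1 of 100 gave as many in each comparison. The real counts were 6936, 6086 and 9698 for continuous, cycling, and cycling against continuous hypoxia, and the highest others were 3773, 0 and 2939. For the counts of called lists chance could not be excluded. The real 20, 4 and 16 lists were reached by 11, 53 and 22 of 100 swaps, and the highest others were 24, 11 and 23. The camera test at its preset correlation is therefore a weak guide to how many lists changed. Sign flips over lines, with Benjamini-Hochberg over 99 tests, called 26, 18 and 24 of 33 lists. Among these were the intestinal, blood cell and fibroblast and endothelial marker lists in continuous hypoxia (adjusted p = 0.00437, 0.0152 and 0.0217) and in cycling against continuous hypoxia (0.000119, 0.0128 and 0.0304). The counts of 26 and 24 thus include small mean shifts in marker lists. In cycling hypoxia against normoxia no marker list was called by the sign flips (adjusted p from 0.509 to 0.94).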
